A study of Mus musculus with 24 samples.

How the data were processed

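The 24 arrays measured total RNA from mouse lung on an Affymetrix murine expression array with one sample per array, per the labels. Each array carried lung RNA from 1 of 2 inbred strains, C57BL/6J or BALB/c, after intratracheal bleomycin at 1.5 U per kg or saline, with lungs taken at 24 h, 72 h or 14 d. Every combination of strain, treatment and time had 2 arrays, marked a and b in the titles. The labels do not say whether a and b were separate animals, so the spread between them may be technical, biological or both, and every p-value below measures only that spread. Groups came from the sample titles. For the BALB/c saline 72 h arrays the titles say saline and the descriptions say bleomycin, and the title was followed. The description of the BALB/c saline 24 h arrays says bleomycin or saline, and the title was followed there too.

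The deposited values are linear intensities, 1 per probe set and array. Calculated from the deposited table, the mean between the 2nd and 98th percentiles lay between 799.8 and 799.9 on every array, from which a scaling to a common trimmed mean before deposit is inferred. No source used here states it. The algorithm that summarised the probes, and any other step between scanner and table, is not given in the sources used here. Raw array images were not used here. The table held 12488 probe sets. The 66 control probe sets were left out of the tests, which left 12422, of which 10833 had one gene name, 396 several and 1193 none in the array annotation. Gene identifiers of 10817 of the one-name probe sets were found in a mouse RefSeq gene table on the reference assembly of strain C57BL/6J, used for names only.

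The following was fixed before the data were examined: the groups, the 15 comparisons, the test, the filter, the gene lists, the rule for named genes and the first set of alternatives. Because the trimmed means differed by far less than 5%, the values were used without further normalization. An offset of 92, the median over arrays of the lower quartile, was added before taking log2. Probe sets above 225.7, the 40th percentile of the whole table, on at least 2 arrays were tested: 8710 in all, 7812 with one gene name, 293 with several and 605 with none. A linear model with a mean for each of the 12 groups was fitted with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom, moderated variances with a trend on intensity, and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05. All tests were two-sided. The comparisons were bleomycin against saline for each strain and time and averaged over the 3 times, the difference between strains in each of these effects (an interaction contrast), the strain difference after saline, and the change of each strain's effect from 24 h to 14 d. The number of arrays limits the precision: simulated data with the spread of these arrays, changed by known amounts in 67, 67 and 66 of 8710 probe sets, gave back 10.4%, 62.7% and 98.5% of log2 changes of 0.5, 1 and 2 in one comparison, with 11 false calls, and 16.4%, 64.2% and 98.5% in another, with 6 false calls.

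Gene-level statements used 1 probe set per gene, the one-name probe set with the highest mean over all arrays, for 6464 genes. For each comparison the named genes were the 10 that rose most and the 10 that fell most among the called genes, up to 4 members with the smallest p of each gene list described, and Blmh, Tgfb1, Timp1, Col1a1, Col3a1, Fn1, Cdkn1a and Acta2 whether or not they were called. Spp1 was also fixed in advance, but none of its probe sets was tested. Genes outside this rule are said to have been chosen after their values were seen. The 28 gene lists held 634 genes, 452 of them tested. Each list was compared with all other genes by camera in limma, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, and adjusted over the 28 lists. In simulated data, with every gene drawn independently, a list shifted by 0.4 on the log2 scale was called at a camera adjusted p of 4.21e-19. Of 27 unshifted lists of the 6464 genes 0 were called. The simulation cannot show how often lists of genes that vary together would be called. Intensities are given as means with the standard deviation of 2 arrays, and log2 changes with the standard error from the model.

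The alternatives were quantile normalization, a smaller or larger offset (46 and 276), no filter or one at the 60th percentile, no variance trend, array weights, the array letter as a block, all saline arrays of a strain as the control, the arrays of a strain alone, the means without the 24 h groups, the mean over a gene's probe sets for the lists, and leaving out each array in turn. After the values were seen, 4 more were added: leaving out the 4 saline arrays of 72 h (with the saline arrays of 24 h and 14 d of the same strain as the control at 72 h, and means over 24 h and 14 d), exchanging the strain labels of those 4 arrays, leaving out 282 very bright probe sets, and using the C57BL/6J saline 14 d arrays as the control at 24 h. Each alternative changed one choice and kept the rest, except that leaving out the 72 h saline arrays also changed the control at 72 h and the times averaged.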

Results

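The data describe gene expression in lungs of 2 mouse strains after intratracheal bleomycin, a drug that damages DNA and is used to produce lung fibrosis in mice, or saline. The series is titled as a study of the genetic basis of sensitivity to pulmonary fibrosis, so the central question is where the strains differ in their response. There were 12 groups of 2 arrays: C57BL/6J and BALB/c, bleomycin and saline, at 24 h, 72 h and 14 d. Median intensities of the arrays ranged from 313 to 408. The log2 values of the 2 arrays of a group correlated across probe sets with r between 0.926 and 0.979 (genes are not independent replicates), and their median absolute difference was 0.13 to 0.29. Xist, which is transcribed from the inactive X chromosome of females, was bright on all arrays (692 to 5047), while the Y-linked genes Eif2s3y (1.78 to 85.8) and Kdm5d (9.55 to 78.6) were dim on all.

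Genes that separate the strains did so on 20 of the arrays but were in reverse on the saline arrays of 72 h. H2-Ea, an MHC class II gene, read 25.6 to 166 on the other C57BL/6J arrays and 2917 to 6068 on the other BALB/c arrays. On the arrays labelled C57BL/6J saline 72 h it read 4821 and 3622, and on those labelled BALB/c saline 72 h 89.5 and 48.3. A panel of 62 genes, selected after this was seen as those that separate the other 20 arrays, placed the 4 arrays between 87.8% and 100.3% of the way toward the other strain, against at most 11.3% for any other array. For comparisons that use these 4 arrays, many values are therefore given as labelled and without them, and values given once are as labelled.

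**Figure D1:**
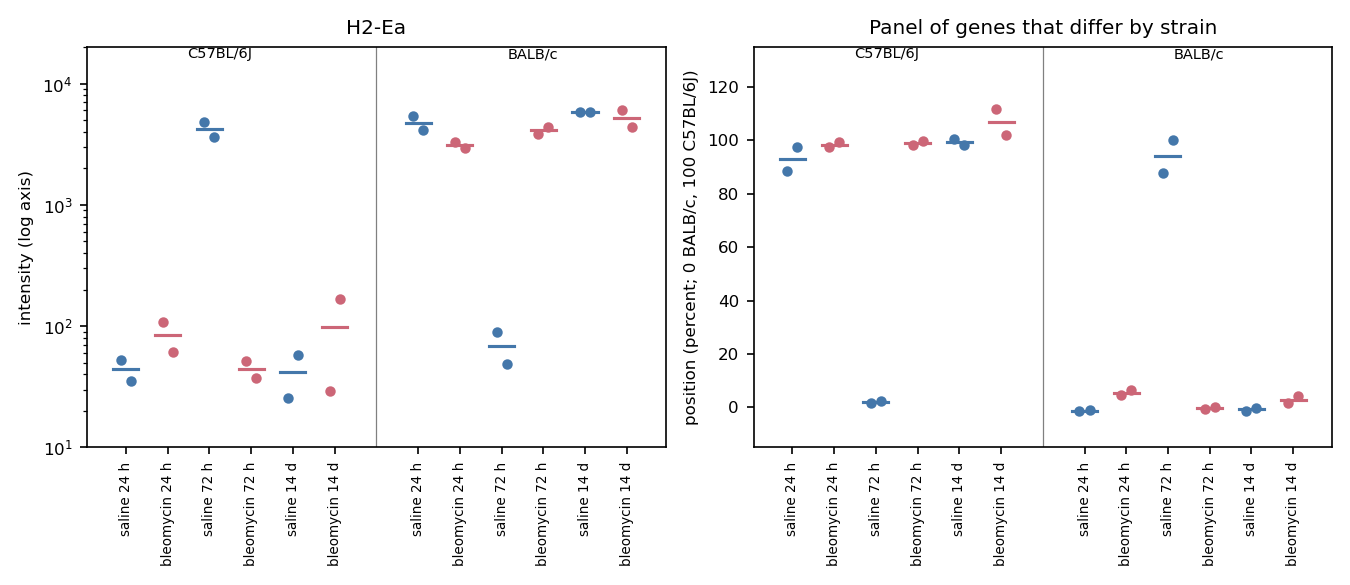
H2-Ea intensity (log axis) and the position on the panel of strain-separating genes (percent, 0 for BALB/c and 100 for C57BL/6J), 1 point per array by group. The saline arrays of 72 h lie with the other strain in both panels, and the other 20 arrays lie with their own.

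In C57BL/6J lungs at 24 h, bleomycin raised genes of the DNA damage response and of the interferon response. Cdkn1a, the p21 cell cycle inhibitor induced by p53, rose from 652 ± 15.4 to 3561 ± 671 (SD, n = 2), a log2 change of 2.28 ± 0.27 (SE, adjusted p = 1.74e-04). Ccng1, another p53 target, rose from 811 ± 81.4 to 3562 ± 391, and Isg15, a ubiquitin-like protein made in response to interferon, from 909 ± 134 to 3672 ± 376 (log2 1.91 ± 0.16, adjusted p = 3.7e-06). Genes of the matrix were not called: Col1a1 differed by -0.06 ± 0.28 (adjusted p = 0.958), Col3a1 by 0.12 ± 0.25, Fn1 by -0.29 and Timp1, an inhibitor of matrix proteases, by 0.49 ± 0.44 (adjusted p = 0.705). Tgfb1 (-0.38), Acta2 (-0.10) and Blmh, the bleomycin hydrolase (0.12, and -0.44 in another probe set), were not called either.

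Of the 17 tested genes of the p53 and DNA damage list at 24 h in C57BL/6J, 7 rose and 10 were not called; adjusted over the list alone 11 rose and 1 fell. Phlda3 (1.89) and Mdm2 (1.43), which restrains p53, were among them, and Gtse1 (2.0) and Ckap2 (1.79), both tied to mitosis, also rose (camera adjusted p = 1.99e-11 for the list, and adjusted p = 0.00442 with an estimated correlation). The interferon list had 7 of 27 genes risen, 16 risen when adjusted over the list alone, and 26 of 27 changes were positive. Ifit1 (1.94), Usp18 (1.63) and Irf7 (1.29) were the other leading members (adjusted p = 6.4e-15, and 0.0407 with an estimated correlation). In the list of cytokines and chemokines 2 of 26 rose, 10 adjusted over the list alone, with Ccl7 (1.84) and Il12b (1.48). In the immediate early and heat shock list 3 of 22 rose, with Fos (1.21) and Hspa1b (1.10). In the unfolded protein response list 1 of 16 rose, Creld2 (0.73). The camera adjusted p values of these lists, 0.00797, 0.0214 and 0.026, became 0.301, 0.301 and 0.363 with an estimated correlation. Of the antioxidant genes Gclc (1.29) and Gpx2 (1.11) rose, while the oxidant defence list as a whole was not called. The lists of MHC class II presentation, B and plasma cells, and the cell cycle leaned lower (camera adjusted p = 0.0174, 0.0214 and 0.0328). By limma 0 of 9, 0 of 13 and 0 of 41 of their genes were called. At an unadjusted p under 0.05, 1 gene was lower in the first list, 1 higher and 3 lower in the second, and 2 higher and 1 lower in the third. None of these leanings held with an estimated correlation (adjusted p = 0.278, 0.301 and 0.521). Collagens and matrix had 0 of 38 genes called by limma, 1 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.255).

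**Figure D2:**
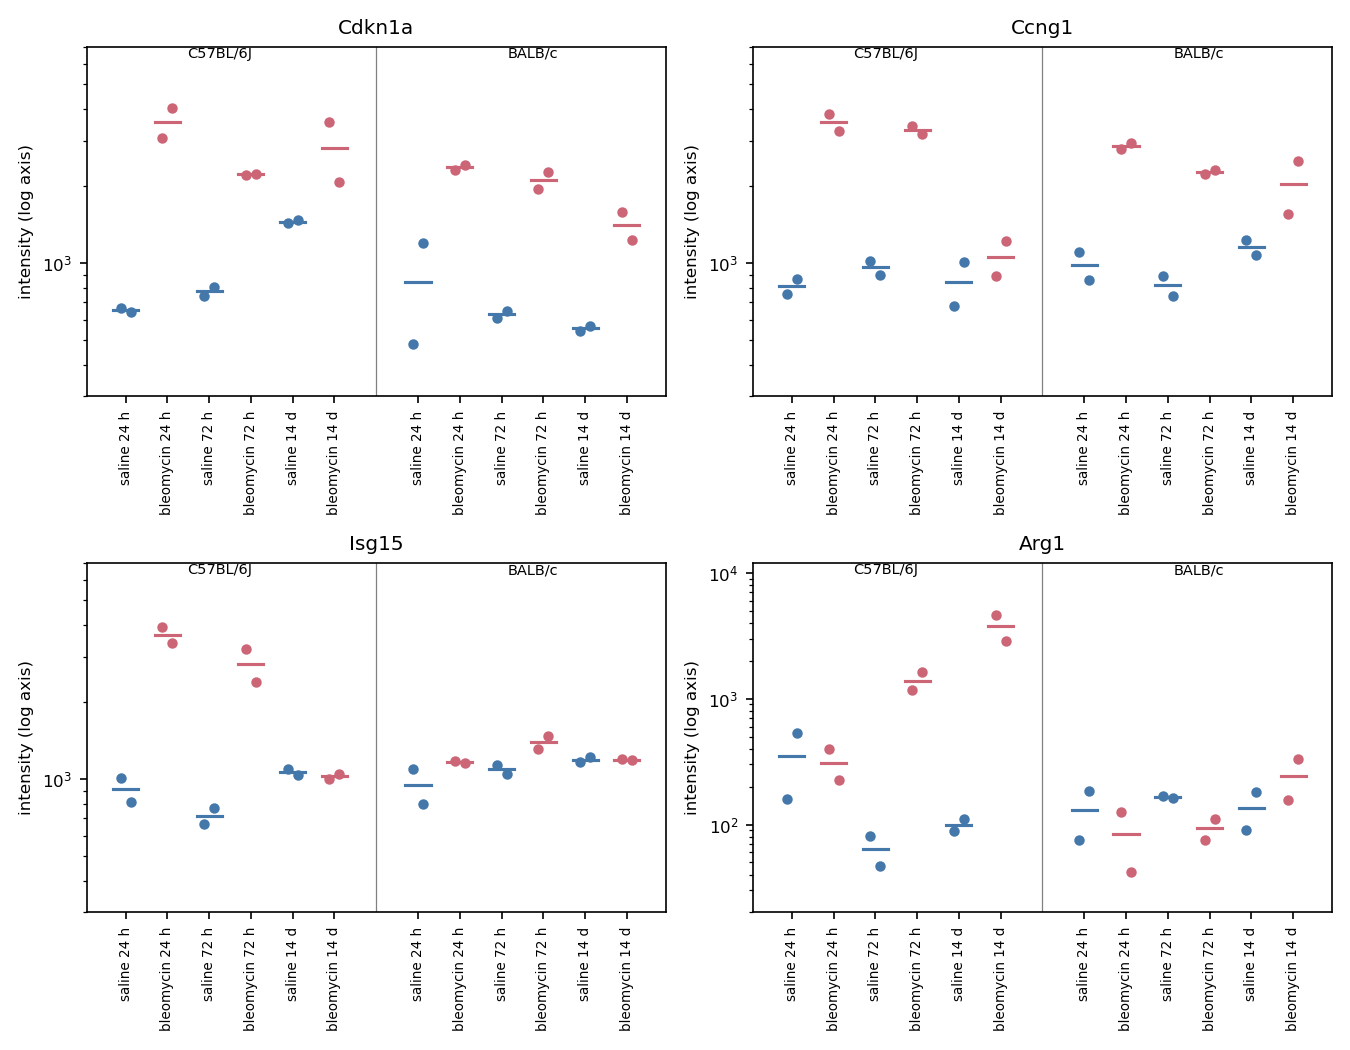
Intensity (log axis) of Cdkn1a, Ccng1, Isg15 and Arg1 at each time, C57BL/6J on the left and BALB/c on the right of each panel, with saline in blue and bleomycin in red. Points are arrays and bars are means of 2 arrays. Arg1 averaged 3778 after bleomycin at 14 d in C57BL/6J and Isg15 averaged 3672 after bleomycin at 24 h in the same strain.

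Among genes that fell in C57BL/6J at 24 h outside the brightest range were Tff2 (-2.61), a secreted mucosal peptide, and Dbp (-1.93), an output gene of the circadian clock. Dbp was no longer called without any 1 of the 4 arrays compared (adjusted p from 0.0535 without the saline b array to 0.197 without the bleomycin a array) and differed by -0.25 against the saline 14 d arrays. The endothelial VEGF receptor Kdr (-1.32, adjusted p = 0.0388) was not called without the bleomycin a (-0.84, adjusted p = 0.439) or saline a array (-0.97, adjusted p = 0.348) or after quantile normalization (0.0569). Against the saline 14 d arrays Kdr read 0.14 higher. The 10 genes with the largest fall, among them Sftpc (-4.90), Scgb1a1 (-4.25), Hba-a1 (-6.15), Rpl41 (-7.05) and Ly6e (-6.52), all belonged to 282 probe sets, called the brightest below, whose mean on the C57BL/6J saline 24 h arrays lay above 6888, the lowest of the array maxima. The 2 arrays of that group, alone in having titles that end in s1, had maxima of 43230 and 78641, against 6888 to 21462 elsewhere. A hybridisation spike added to all samples (CreX, 3' probe set) read 20886 and 32222 there against 4629 to 17491 elsewhere. With the C57BL/6J saline 14 d arrays as the control, Sftpc read 2.28 higher in place of lower, Scgb1a1 1.02 higher and Hba-a1 0.63 higher. Alveolar type 2 genes fell for 3 of 12 (8 adjusted over the list alone, Sftpc and Lpcat1 among them; camera adjusted p = 1.44e-10, 0.035 with an estimated correlation), and airway epithelial genes for 3 of 10 (4.36e-05 and 0.034). Alveolar type 1 genes fell for 2 of 9 (0.00797, and adjusted p = 0.145 with an estimated correlation) and endothelial genes for 2 of 25 with 1 risen, Lyve1 (0.00171, and 0.163). Without the brightest probe sets the type 2 list stayed lower (adjusted p = 1.61e-04) and the airway list (0.0613) and type 1 list (0.631) were no longer called.

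**Figure D3:**
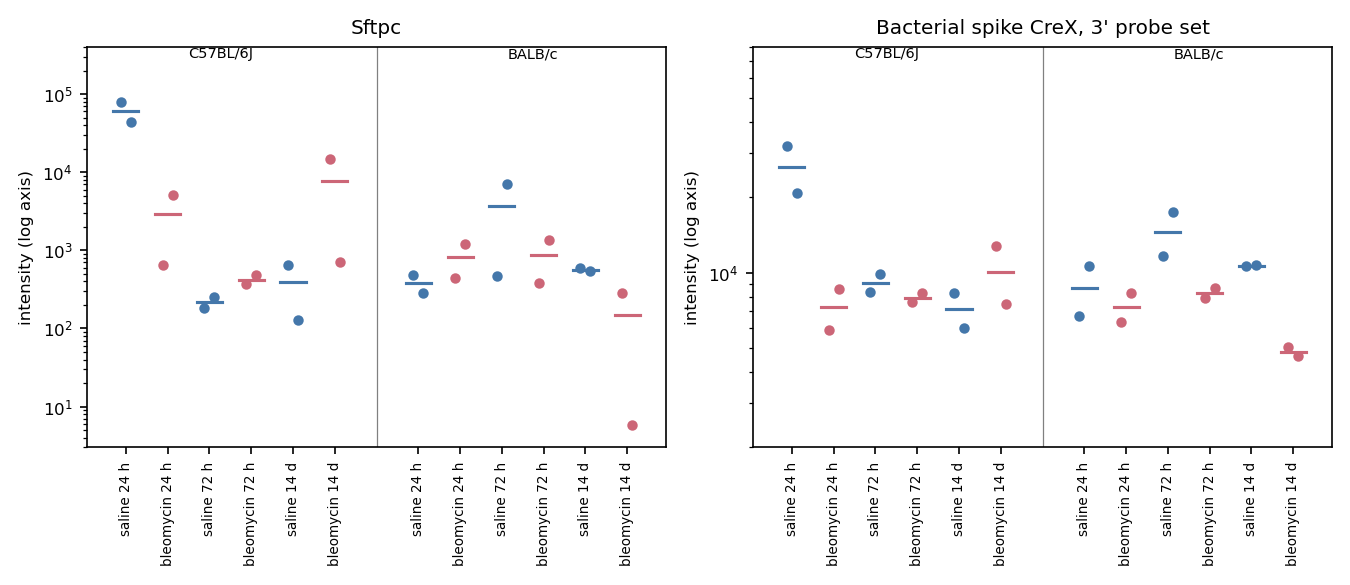
Intensity (log axis) of Sftpc and of the CreX 3' spike control on each array, by group. Both are highest on the C57BL/6J saline 24 h arrays, the only arrays with the title suffix s1, where Sftpc read 43230 and 78641.

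Across all genes, 194 of 8710 probe sets were called in C57BL/6J at 24 h, 104 higher and 90 lower, 45 of them among the brightest (1275 had an unadjusted p under 0.05). The count was 38 without the bleomycin a array, 99 without the bleomycin b array and 53 without the saline a array of this comparison. It was 126 without the brightest probe sets, 121 after quantile normalization and 460 with the saline 14 d arrays as the control.

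In BALB/c at 24 h few genes were called, with 3 p53 targets among them. Ccng1 rose from 978 ± 173 to 2863 ± 104 (n = 2; log2 1.48 ± 0.21, adjusted p = 0.0056), Cdkn1a by 1.52 ± 0.27 (adjusted p = 0.0298). Phlda3, which binds membrane lipids and restrains Akt, rose by 1.03 (adjusted p = 0.0446). Also higher were Psapl1 (1.29), Mxd4 (1.12), a repressor of Myc target genes, and Cox6b2 (0.99). Lower were the kinase gene Tec (-1.71), the lymphocyte antigen Cd52 (-0.84), Bdnf (-0.83) and the RNA polymerase subunit Polr2g (-0.80). Col1a1 (0.05), Col3a1 (-0.18), Timp1 (0.03), Tgfb1 (0.09), Fn1 (0.09), Acta2 (0.34) and Blmh (0.06) were not called. Of the p53 list 3 of 17 genes rose, 9 adjusted over the list alone (camera adjusted p = 2.16e-04, and adjusted p = 0.144 with an estimated correlation), and no other list was called, the interferon list included (0.712). In all, 19 probe sets were called, 11 higher and 8 lower, with 1182 at an unadjusted p under 0.05. The count was 1 without the bleomycin b array, 4 without the saline a array and 52 without the saline b array, and 228 with the saline arrays of all 3 times as the control. Arrays of other groups, which enter through the shared estimate of the spread, moved it to between 10 and 35. Ccng1 was not called without the bleomycin b array (1.44, adjusted p = 0.169), and Cdkn1a without the bleomycin a (0.0925), bleomycin b (0.378) or saline a array (0.93, adjusted p = 0.207). Phlda3 was not called without any 1 of the 4 arrays compared (adjusted p from 0.0647 without saline b to 0.416 without bleomycin b). Without the bleomycin b array none of the other 7 genes named as higher or lower was called (adjusted p from 0.289 for Psapl1 to 0.437 for Cd52), and without the saline a array only Cox6b2 was (0.132 for Bdnf to 0.311 for Mxd4). Without the bleomycin a array Psapl1, Mxd4, Tec, Cd52 and Polr2g were not called (0.0858 for Psapl1 to 0.122 for Mxd4), nor Cox6b2 without the saline b array (0.057). Without the 4 saline arrays of 72 h, which lie outside this comparison, Cdkn1a, Phlda3, Mxd4, Tec and Cd52 (each 0.0565) and Polr2g (0.0523) were not called. With the arrays of BALB/c alone Cdkn1a (0.0522), Mxd4 (0.0625), Tec (0.0731), Cd52 (0.0525) and Polr2g (0.0522) were not called. Without the filter Phlda3 (0.0584), Mxd4, Tec and Cd52 (each 0.0698) were not, nor Mxd4 (0.0528) and Cd52 (0.0555) without the variance trend or Tec with array weights (0.0548).

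The strains differed in the 24 h response in Isg15, whose rise was larger in C57BL/6J by 1.62 ± 0.23 on the log2 scale (n = 2 arrays per group; adjusted p = 0.0127). The interferon list as a whole rose more in C57BL/6J: 24 of 27 differences were positive, 1 gene was called and 13 adjusted over the list alone (camera adjusted p = 4.51e-11, and adjusted p = 0.127 with an estimated correlation). Isg15 was not called without the C57BL/6J bleomycin a array (1.52, adjusted p = 0.157) or the BALB/c bleomycin b array (1.61, adjusted p = 0.113). The p53 list also rose more (0.00188, and 0.127), with 0 of 17 genes called by limma and 7 higher at an unadjusted p under 0.05, and Cdkn1a alone did not differ (0.77, adjusted p = 0.549). The unfolded protein response and cytokine lists leaned toward C57BL/6J (2.26e-04 and 0.0163), and the type 2, airway, endothelial and red cell lists toward BALB/c (6.5e-05, 3.85e-04, 0.0289 and 0.0223); none of the 8 held with an estimated correlation. The other called probe set was one for Glul, glutamine synthetase (-2.11, chosen after its value was seen). Collagen genes did not differ (Col1a1 -0.10, Col3a1 0.31), nor did Timp1 (0.45), Tgfb1 (-0.46), Fn1 (-0.38), Acta2 (-0.44) or Blmh (0.06, and -0.87 in another probe set). Only 2 probe sets were called, with 840 at an unadjusted p under 0.05. The count was 0 by limma without the C57BL/6J bleomycin a array (648 unadjusted) or without the BALB/c bleomycin b array (564 unadjusted). It was 1 without the C57BL/6J saline a or bleomycin b array, 4 without the BALB/c saline b array or either array labelled BALB/c saline 72 h, 6 without either C57BL/6J bleomycin 14 d array, and 27 without the C57BL/6J saline b array.

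At 72 h in C57BL/6J, values are given as labelled and then without the saline arrays of 72 h. Chemokines of monocytes rose: Ccl2 rose by 4.06 ± 0.72 (3.11 without), Ccl7 by 3.03 (2.37) and Ccl8 by 2.08 (1.86). Clca3a1, a secreted regulator of chloride channels, rose from 113 ± 40.6 to 2206 ± 615 (n = 2; log2 3.48 ± 0.25, adjusted p = 1.46e-07, and 3.28 without), and Arg1, arginase, by 3.24 ± 0.40 (2.41). A bright probe set for Lcn2 was higher as labelled (3.23, adjusted p = 0.033) and not without (0.94, adjusted p = 0.534), and its second probe set did not change (0.01). The p53 targets Ccng1 (1.69, 1.90 without) and Cdkn1a (1.42, 1.11) stayed high. Col3a1 was called as labelled (1.13 ± 0.25, adjusted p = 0.0104) and not without those arrays (0.55, adjusted p = 0.167), nor without the bleomycin a (0.0542), bleomycin b (0.0897) or saline b array (0.105). Timp1 (1.40, adjusted p = 0.0692, and 0.87 without), Col1a1 (0.82 and 0.23), Fn1 (-0.05 and -0.10), Acta2 (-0.06 and 0.16) and Blmh (0.12 and -0.06) were called in neither form, and Tgfb1 was lower without those arrays (-1.13, adjusted p = 0.0294) but not as labelled (-0.24).

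Ccl17 (3.01, and 1.50 without) and Mmp3 (2.73, and 1.46) were higher in both forms, though Mmp3 was not called with the strain labels of those arrays exchanged (1.35, adjusted p = 0.114). Xdh (2.77, and 0.71 without, adjusted p = 0.0739) and Reg3g (2.64, and 0.17) were higher as labelled only. The strain-separating genes H2-Ea (-4.97, 0.02 without), Gbp2b (-3.34, -0.20), Baiap2l1 (-2.49, -0.21) and Fbp2 (-2.26, 0.04) were lower as labelled only. One probe set for Pdxdc1 was lower as labelled (-5.20, -0.55 without) while 2 others were higher (2.56 and 1.82), so the gene has no one direction. Without them, Gm9706 (2.10), Sprr1a (1.96), a cornified envelope gene, Mmp8 (1.94) and Kng1 (1.83) were also higher, and Dynll2 (-2.27), Lfng (-2.07), a modifier of Notch, Hc (-2.05), complement C5, and Tff2 (-2.0) lower. The p53 list had 9 of 17 genes risen (10 without; camera adjusted p = 5.45e-07 and 1.4e-08; as labelled 0.0215 with an estimated correlation). The interferon list had 11 of 27 (10 without; 2.27e-12 and 8.59e-09; 0.0714 with an estimated correlation), cytokines 8 of 26 (6 without; 4.44e-06 and 0.0134) and complement 5 of 12 (3 without; 7.25e-04 and 0.00679). Heart and skeletal muscle genes fell for 6 of 17 (4 without, camera adjusted p = 2.91e-06 and 3.91e-04). Myh7, outside that list, was also lower as labelled (-1.91). Lists of type 2 activation (4 of 13 risen, 2.91e-06, 0.0215 with an estimated correlation), macrophages (5 of 24, 3.36e-06), proteases (3 of 18 risen, 1 fallen, 0.00592), collagens (8 of 38 risen, 1 fallen, 0.0195) and neutrophils (1 of 9, 0.0424) were called as labelled and not without those arrays. Alveolar type 2 genes were lower without them (3 of 12, camera adjusted p = 5.37e-05). The control then included the C57BL/6J saline 24 h arrays (Sftpc 78641 and 43230). That fall cannot be told apart from their high bright signals. With an estimated correlation only the p53 and type 2 activation lists held as labelled (adjusted p of the other lists named from 0.0714 for complement to 0.286 for neutrophils). As labelled 576 probe sets were called, 359 higher and 217 lower, against 522 without the 4 arrays, 209 of them shared, and 226 with their strain labels exchanged. Leaving out 1 array gave 222 (saline b), 341 (saline a), 229 and 237 (bleomycin a and b).

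In BALB/c at 72 h the genes called in both forms included p53 targets, Ccl8, Bcl3 and Irf7, and also Gatm, a creatine synthesis enzyme (2.34, and 0.84 without the saline arrays of 72 h), and Xdh (-2.12 and -1.08). Cdkn1a rose from 628 ± 29.8 to 2111 ± 233 (n = 2; log2 1.61 ± 0.27, adjusted p = 0.003, and 1.56 ± 0.25 without the saline arrays of 72 h). Ccl8 rose by 2.02 ± 0.27 (1.79), Bcl3, a regulator of NF-kappaB, by 1.48 (1.36), and Irf7, which drives interferon genes, by 1.09 (1.28). Col1a1 (0.00, 0.67 without), Col3a1 (0.07, 0.39), Timp1 (0.52, -0.26), Tgfb1 (0.08, -0.09), Fn1 (-0.12), Acta2 (0.05, 0.82) and Blmh (-0.20, -0.30) were not called in either form. As labelled, the largest rises included strain-separating genes, one probe set for Pdxdc1 (4.75, with 2 others lower at -1.62 and -1.69), H2-Ea (4.72), Gbp2b (3.82) and Fbp2 (2.54). Erdr1 (2.64, with a second probe set at 0.24) lay between Gbp2b and Fbp2. H2-Ea was at -0.35 without the doubtful arrays. Without them the histone gene H3c14 (2.52), the antibacterial lectin Reg3g (2.12), Zbtb16 (1.64), Itgb4 (1.55), Phlda1 (1.40) and Klf2 (1.28) were higher. Lower were Pdc (-1.78), Bcl2l10 (-1.72), Rraga (-1.64), Atp8a1 (-1.45) and Igfbp3 (-1.43). None of these was called as labelled. Tff2 (-2.89) and Rbfox2 (-2.76) were among the genes lower as labelled only.

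Of the p53 list in BALB/c at 72 h, 3 of 17 genes rose (5 without; camera adjusted p = 2.99e-05 and 1.07e-06; as labelled 0.0816 with an estimated correlation). Of the interferon list 1 of 27 rose (6 without; 1.87e-04 and 6.47e-08; 0.475 with an estimated correlation). Cytokines (1 of 26, 0.0203), airway genes (1 of 10 fallen, 0.00142) and red cell genes (1 of 4 fallen, 0.0203) were called as labelled and not without. So were MHC class II (lower, 0 of 9 by limma and 3 at an unadjusted p under 0.05, 0.00179) and alveolar type 2 genes (lower, 0 of 12 by limma and 1 unadjusted, 0.0197). None of these 5 held with an estimated correlation (adjusted p from 0.106 for airway genes to 0.505 for cytokines). Myofibroblast and smooth muscle genes (2 of 16 risen, 8.53e-04) and collagens (3 of 38, 0.0178) were called without those arrays and not as labelled. As labelled 115 probe sets were called, 54 higher and 61 lower, against 526 without the 4 arrays, 19 of them shared, and 7 with their strain labels exchanged. In that last form Ccl8 (2.15, adjusted p = 0.0034) and the p53 target Ccng1 (1.16, adjusted p = 0.0492) were called, and Cdkn1a (1.35, adjusted p = 0.0902), Irf7 (0.92, adjusted p = 0.176), Bcl3 (0.53), Gatm (0.71) and Xdh (-0.07) were not. The count was 52 without 1 array (bleomycin b), 61 (bleomycin a), 64 and 66 (saline a and b). Without the bleomycin b array Cdkn1a (1.50, adjusted p = 0.0657) and Irf7 (0.92, adjusted p = 0.233) were not called, and Irf7 was not called without the saline a (0.122) or b array (0.0805).

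Among the strain differences at 72 h present in both forms was Arg1. It was higher in the C57BL/6J response by 3.72 ± 0.57 as labelled (n = 2; adjusted p = 6.15e-04) and by 2.66 ± 0.52 without the saline arrays of 72 h (adjusted p = 0.031). The response was also higher in C57BL/6J in both forms for Clca3a1 (3.01 and 2.36), Sprr1a (2.65 and 2.04), Tex2 (1.97 and 1.83) and Xdh (4.89 and 1.79), xanthine dehydrogenase. Without those arrays the Xdh difference came with a called fall in BALB/c and no called rise in C57BL/6J. For Lrp5, a Wnt co-receptor, the response was lower in C57BL/6J (-1.73 and -1.97). With the strain labels of those arrays exchanged, none of these was called: Arg1 differed by 2.27 (adjusted p = 0.453), Clca3a1 by 2.08 (0.15), Sprr1a by 1.89 (0.432), Tex2 by 1.35 (0.551) and Xdh by 0.78 (0.769), and Lrp5 had the opposite sign (0.63, adjusted p = 0.873). In that form 0 probe sets were called by limma, with 561 at an unadjusted p under 0.05. As labelled the extremes again included genes that separate the strains, one probe set for Pdxdc1 (-9.95, with 2 others at 4.18 and 3.51), H2-Ea (-9.69), Gbp2b (-7.16), Chil3 (3.98) and Mir686 (5.33). Without the 4 arrays, Pam (2.08), Azgp1 (1.71) and Hsd17b7 (1.57) were higher and H3c14 (-2.99), Cdh13 (-2.67), Tubb4a (-1.77) and Cnn1 (-1.36), calponin of smooth muscle, lower. Col1a1, Col3a1, Timp1, Tgfb1, Fn1, Cdkn1a, Acta2 and Blmh were called in neither form; Timp1 differed by 0.88 and 1.13, Tgfb1 by -0.31 and -1.04. Of the 8 lists called as labelled, type 2 activation had 4 of 13 genes higher (2.52e-06, 0.0299 with an estimated correlation), the interferon list 4 of 27 (6.71e-05, 0.433), macrophages 1 of 24 (5.33e-04) and the immediate early list 2 of 22 (8.32e-04). The complement (0.0423), cytokine (0.0423) and airway (0.0193) lists leaned the same way. Heart and muscle genes were lower in both forms, with 6 of 17 as labelled (camera adjusted p = 3.1e-05). Without those arrays 0 of 17 were lower by limma and 4 unadjusted (camera adjusted p = 0.0394). Alveolar type 2 genes were lower without those arrays (camera adjusted p = 0.00173). The C57BL/6J control then included the saline 24 h arrays with their high bright signals. As labelled, only type 2 activation of the 8 held with an estimated correlation (adjusted p from 0.283 to 0.61 for the others). As labelled 268 probe sets were called, 159 higher and 109 lower, and 79 without the 4 arrays, 13 of them shared. With 1 array fewer the count was 154 or 177 (BALB/c bleomycin a or b) and 178 (C57BL/6J bleomycin a).

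In C57BL/6J at 14 d, genes that rose included macrophage, chemokine and matrix genes. Arg1 rose from 99.4 ± 15.5 to 3778 ± 1237 (SD, n = 2), a log2 change of 4.30 ± 0.40 (adjusted p = 1.89e-05). The chemokine Ccl8 rose from 47.8 ± 7.2 to 1070.2 ± 274, the macrophage elastase Mmp12 by 2.95 ± 0.40, the complement gene C1qb by 2.94 ± 0.33 (0.23 in a second probe set, not called) and the matrix glycoprotein Tnc by 2.46 ± 0.28. Timp1 rose by 1.57 ± 0.44 (adjusted p = 0.0372) and Col3a1 by 0.87 ± 0.25 (adjusted p = 0.0419). Col1a1 (0.56, adjusted p = 0.258), Cdkn1a (0.87, adjusted p = 0.0638), Acta2 (0.67, adjusted p = 0.166), Tgfb1 (0.17, adjusted p = 0.812), Fn1 (-0.14) and Blmh (-0.03) were not called, though another probe set for Col1a1 was called at 0.92. Timp1 and Col3a1 were not called without the bleomycin a array (0.80, adjusted p = 0.471, and 0.34, adjusted p = 0.546), the saline a array (adjusted p = 0.16 and 0.147) or the saline b array (0.101 and 0.129). Nor were they called with array weights (0.113 and 0.108), or Col3a1 after quantile normalization (0.0761).

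Other genes with large rises at 14 d in C57BL/6J were Fst (3.15), an activin inhibitor, Cpxm1 (2.38), Ccl2 (2.72) and Saa3 (4.43, adjusted p = 0.0347, a bright probe set). Without the bleomycin a array Ccl2 (2.05, adjusted p = 0.305) and Saa3 (3.83, adjusted p = 0.278) were not called. Some genes of B cells and vessels were lower: Cd79b (-1.25), Cd79a (-1.15) and Ms4a1 (-1.17) of B cells, and Thbd (-1.38), Icam2 (-1.19), Car4 (-1.09) and Tie1 (-1.06) of endothelium. Hc (-2.01), Pon1 (-1.97), Csrp3 (-1.81), Chil1 (-1.77), the chaperone Hsph1 (-1.61), Mapt (-1.55), Traf1 (-1.53) and Bpifb1 (-1.48) had the largest falls. One bright probe set for Eln, elastin, was lower (-2.79) while a second one read higher (1.94), and Hspa4 (-1.49) had 3 other probe sets of opposite sign, so neither gene has one direction.

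The collagen and matrix list at 14 d in C57BL/6J had 11 of 38 genes risen and 3 fallen, 16 and 3 adjusted over the list alone (camera adjusted p = 1.95e-08, 0.0195 with an estimated correlation). Fbln2 (1.95), Ccn2 (1.88), connective tissue growth factor, and Col5a2 (1.64) were among the risen. Matrix proteases and their inhibitors had 10 of 18 risen, 12 adjusted over the list alone, with the cathepsins Ctsk (1.81) and Ctsb (1.22) (3.05e-11, and 0.0195). Macrophage markers had 9 of 24 risen, 16 adjusted over the list alone, Cd68 (1.54) and Fcgr2b (1.88) among them (1e-13, and adjusted p = 0.0541 with an estimated correlation), and complement 4 of 12 (1.15e-04, and 0.036). Cytokines (4 of 26 risen, 5.47e-04), the cell cycle (3 of 41, 2.39e-05), coagulation (2 of 13 risen and 1 fallen, 0.00203), p53 (3 of 17, 0.00762) and type 2 activation (2 of 13, 0.0372) were higher. Endothelial genes (9 of 25 fallen, 4.15e-04), heart and skeletal muscle genes (7 of 17, 4.1e-04), B and plasma cell genes (4 of 13, 7 adjusted over the list alone, 6.5e-04) and T and NK cell genes (1 of 13, 0.0249) were lower. None of these 9 held with an estimated correlation (adjusted p from 0.0795 for coagulation to 0.32 for T and NK cells). The interferon list was not called (0.305; 1 risen, 3 fallen). The bleomycin a array is the only one with a title ending in s2a. Sftpc read 14576 on it against 710 on the bleomycin b array, and Scgb1a1 16391 against 3855. Its maximum was 19576 against 11477. Of the CreX spike the 3' probe set was higher (12742 against 7477) and the 5' probe set lower (7339 against 8182). Whether this array was measured differently was not tested. In all 647 probe sets were called, 271 higher and 376 lower, 8 among the brightest. Without the bleomycin a array the count was 87 and without the bleomycin b array 1249; without the saline a or b array it was 291 or 312, and with array weights 175.

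In BALB/c at 14 d, the genes that rose included chemokine, complement and cell cycle genes. Ccl8 rose from 44.2 ± 3.5 to 833 ± 190 (SD, n = 2), a log2 change of 2.75 ± 0.27 (adjusted p = 5.51e-05), and the matrix glycoprotein Tnc by 1.72 ± 0.28. Cdk1, the mitotic kinase, rose by 1.36, and Tgfb1 from 512 ± 95.4 to 1362 ± 97.7 (log2 1.28 ± 0.32, adjusted p = 0.0161). Cdkn1a rose by 1.20 ± 0.27 (adjusted p = 0.01) and Fn1, fibronectin, fell by 1.46 (adjusted p = 0.0168). Timp1 (0.03, adjusted p = 0.973), Col1a1 (0.75, adjusted p = 0.0923), Col3a1 (0.38, adjusted p = 0.337), Acta2 (0.64, adjusted p = 0.146) and Blmh (-0.46, adjusted p = 0.0577) were not called. Of the 2 other probe sets for Col3a1 (1.38 and 0.28), however, 1 was called higher. Another probe set for Blmh had the opposite sign (0.37). Tgfb1 was not called without the bleomycin b (1.21, adjusted p = 0.125), saline a (0.129) or saline b array (0.0554). The same held for Fn1 without the bleomycin b (-0.64, adjusted p = 0.29), saline a (0.0768) or saline b array (0.111), and for Cdkn1a without the saline a (0.0727) or b array (0.0583).

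The linker histone H1f10 (2.52), Glipr2 (2.40), H3c14 (2.27), the metalloprotease Adam8 (2.07), Mast2 (2.06), the metallothionein Mt2 (2.02), Cpxm1 (1.99) and Kng1 (1.93) were other large rises at 14 d in BALB/c. Ccl2 (2.26 ± 0.72, adjusted p = 0.0464) was not called without any 1 of the 4 arrays compared (adjusted p from 0.0605 without the bleomycin a array to 0.269 without the bleomycin b array). Of the 10 genes with the largest falls, Sct, secretin, (-4.10) was the only one outside the brightest probe sets, and its second probe set was not called (-0.30, adjusted p = 0.529). Rnf10 (-4.43), Ager (-3.88), Scgb1a1 (-3.68), Ctsd (-3.56) and Lamp1 (-3.38) were within them. For Eln a bright probe set was lower (-4.08) and another higher (2.48). The BALB/c bleomycin 14 d arrays also had the lowest readings of the CreX spike, 5036 and 4629 against 10637 and 10721 on the saline arrays. Falls of bright probe sets here were thus accompanied by a fall in a spike that does not come from the lung.

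Cell cycle genes rose for 17 of 41 in BALB/c at 14 d, 18 risen and 1 fallen adjusted over the list alone (camera adjusted p = 1.05e-05, and adjusted p = 0.315 with an estimated correlation). They included Cks1b (1.15), Mad2l1 (1.0) and Ccnb2 (0.92). Collagens and matrix had 13 of 38 risen and 3 fallen, 16 and 4 adjusted over the list alone, with Tnc, Col6a2 (1.17) and Col7a1 (1.08) (0.0155, and 0.315). Complement had 5 of 12 risen with C1qa (1.55) and C3ar1 (1.70) (0.0408), macrophage markers 7 of 24 risen and 3 fallen (0.0408) and cytokines 3 of 26 risen (0.0433). Alveolar type 1 (2 of 9 fallen, with Emp2 at -1.29, 0.0155), alveolar type 2 (3 of 12, 0.0408), airway (3 of 10 fallen, 1 risen, 0.0408) and endothelial genes (2 of 25, with Ednrb at -1.26, 0.0408) were lower. Bmpr2, a member of the TGF-beta pathway list, was at -1.03. None of these 9 lists held with an estimated correlation, and without the brightest probe sets the type 2 median was 0.16 in place of -0.83. Proteases were not called as a list (0.284; 4 risen, 1 fallen), though Mmp3 (1.76), Mmp12 (1.56) and Ctsk (1.42) rose. In all 1158 probe sets were called, 688 higher and 470 lower, 102 among the brightest. Without the bleomycin b array the count was 198, and without the saline a or b array it was 271 or 319.

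**Figure D4:**
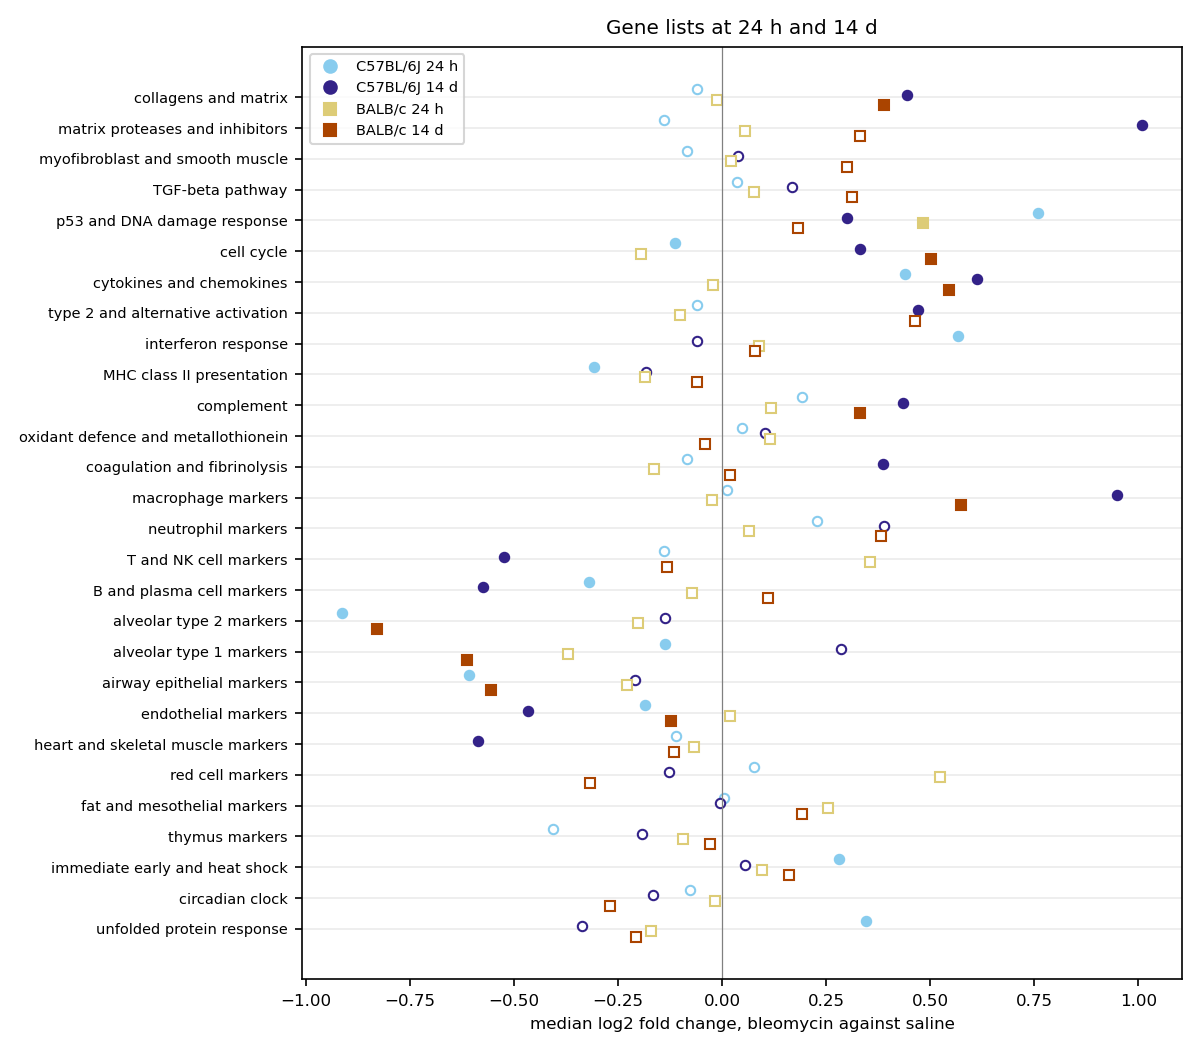
Median log2 change after bleomycin over the tested genes of each list, for C57BL/6J and BALB/c at 24 h and 14 d; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. At 14 d the protease list had a median of 1.01 in C57BL/6J, and the cell cycle list a median of 0.50 in BALB/c.

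Both strains shared part of the 14 d response: 90 probe sets were called higher in both, where independent lists of these sizes would share 21.4. Of those called higher in C57BL/6J, 8 were called lower in BALB/c. The spread of each probe set was estimated from all 24 arrays. That can favour the same ones in both strains, so independent lists are only a rough reference. For lower probe sets the overlap was 15 against 20.3 for independent lists, and 17 called lower in C57BL/6J were called higher in BALB/c. At 24 h 7 probe sets were called higher in both strains against 0.131. For lower ones 0 were shared by limma against 0.0827 (70 lower in both at an unadjusted p under 0.05), and 1 called lower in C57BL/6J was called higher in BALB/c. At 72 h, with the labels as given, opposite calls outnumbered shared ones: 16 were higher in both against 2.23, and 31 higher in C57BL/6J were lower in BALB/c. For lower ones 4 were shared against 1.52, and 20 were opposite.

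The strains differed at 14 d in Sct, whose response was higher in C57BL/6J by 6.18 on the log2 scale (n = 2 arrays per group, adjusted p = 4.37e-04), and in Arg1, which rose more in C57BL/6J by 3.76 ± 0.57 (adjusted p = 0.00244). Fbln2, a matrix glycoprotein, rose more in C57BL/6J by 1.74, Ccn2 by 1.02 and Msln, a mesothelial protein, by 0.99. Sct, Arg1 and Fbln2 were called under every setting, but a second probe set for Sct was not called (0.90, adjusted p = 0.183). Ccn2 was not called after quantile normalization (0.47, adjusted p = 0.387) or Msln with array weights (0.0957), and neither was called without the C57BL/6J bleomycin a array (0.117 and 0.0623). Genes whose response was lower in C57BL/6J included the cadherin Cdh13 (-2.32), the nucleotide enzyme Dut (-2.31), Get4 (-2.20), Lrp5 (-2.13), Lsm2 (-2.04), Six5 (-2.01), the receptor kinase Tyro3 (-2.01), Hsph1 (-2.0), Chil1 (-1.99) and the integrin Itgb4 (-1.95). The B cell gene Cd79b (-1.53) and the endothelial genes Thbd (-1.39) and Car4 (-1.29) were also lower, though the endothelial list was not called (2 of 25 lower, 0.46). Cd79b was not called without either BALB/c array b (bleomycin 0.0639, saline 0.0765), without the C57BL/6J bleomycin a (0.0585) or saline b array (0.0545), or with array weights (0.0557). The genes fixed in advance did not differ by test: Tgfb1 (-1.11, adjusted p = 0.143), Timp1 (1.54, adjusted p = 0.138), Col3a1 (0.49, adjusted p = 0.423), Col1a1 (-0.18), Fn1 (1.32, adjusted p = 0.132), Cdkn1a (-0.34), Acta2 (0.03) and Blmh (0.42, adjusted p = 0.241).

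Of the 10 genes with the largest positive difference at 14 d, 9 were bright probe sets, such as Scgb1a1 (6.46), Sftpb (5.75) and Ager (5.70), and the remaining one was Sct. Scgb1a1 read 16391 on the C57BL/6J bleomycin a array, the only array with a title ending in s2a, and 3855 on the b array. Matrix proteases leaned toward C57BL/6J, with 16 of 18 differences positive (camera adjusted p = 2.56e-04, and adjusted p = 0.278 with an estimated correlation). By limma 0 of their genes were called, also when adjusted over the list alone, and 8 were higher at an unadjusted p under 0.05. Macrophage markers (2 of 24 higher, 3.9e-04, and 0.516), coagulation genes (1 of 13 higher and 1 lower, 0.0205, and 0.278) and alveolar type 1 genes (2 of 9 higher, 0.00779, and 0.278) also leaned toward C57BL/6J. B and plasma cell genes were lower (2 of 13, 6 adjusted over the list alone, 0.00779, and 0.426). Without the brightest probe sets the type 1 list was no longer called (0.261). Collagens (0.0894) and the cell cycle (0.46) did not differ as lists. In all 647 probe sets were called, 222 higher and 425 lower, 59 among the brightest, around a median difference of all probe sets of -0.10. Leaving out 1 array moved this count to 136 or 161 (BALB/c saline b or a), 170 or 990.0 (BALB/c bleomycin b or a), 303 or 1014 (C57BL/6J bleomycin a or b) and 382 or 325 (C57BL/6J saline a or b).

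From 24 h to 14 d the C57BL/6J response became smaller for some interferon and p53 genes and larger for some matrix and macrophage genes. Arg1 rose by 4.32 more at 14 d than at 24 h, Mmp12 by 2.48, Ctsk by 2.26, Fbln2 by 2.09 and Col1a2 by 1.57. Mmp12 was not called when any of 4 arrays was left out singly, with adjusted p up to 0.137 (bleomycin 14 d a). Isg15 was lower by 1.96 ± 0.23 on the log2 scale (-1.96, n = 2, adjusted p = 4.58e-04), Usp18 (-2.03), Ifit1 (-1.96), Ccng1 (-1.72), Mdm2 (-1.09) and the heat shock genes Hsph1 (-2.21) and Hspa1b (-1.96) likewise. Cdkn1a (-1.42, adjusted p = 0.0594), Timp1 (1.09), Col3a1 (0.74), Col1a1 (0.62), Acta2 (0.77), Tgfb1 (0.55), Fn1 (0.15) and Blmh (-0.15) were not called. Of the 2 other probe sets for Col3a1 (1.65 and 0.55), 1 was called higher. Collagens had 9 of 38 genes with a larger response at 14 d and 1 with a smaller one (10 and 3 adjusted over the list alone; camera adjusted p = 8.37e-09, 0.0263 with an estimated correlation), proteases 4 of 18 (3.36e-10, and 0.0281) and macrophage markers 4 of 24 (6.72e-13, and 0.065). The interferon list had 6 of 27 with a smaller one (16 adjusted over the list alone; 6.08e-10, and 0.083). The p53 list had 4 of 17 smaller (0.0016, and 0.083) and the myofibroblast list 1 of 16 larger (0.0243, and 0.252). The 10 largest positive changes were all bright probe sets, Ly6e (8.89) and Sftpc (7.99) among them, which rest on the s1 arrays. In all 236 probe sets were called, 125 higher and 111 lower, 39 among the brightest, around a median of -0.12. Single omissions gave 69 or 848 (bleomycin 14 d a or b), 89 or 120 (bleomycin 24 h a or b), 94 (saline 14 d b) and 153 (saline 24 h a), and array weights 116.

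In BALB/c the response from 24 h to 14 d became larger for some cell cycle genes. Cdk1 rose by 2.35 ± 0.30 more at 14 d (n = 2, adjusted p = 0.00177), Uhrf1, a DNA methylation maintenance factor, by 2.43, Cks1b by 1.66, Cdc20 by 1.34 and Ccnb2 by 1.11. Uhrf1 was not called when any of 4 arrays was left out singly, with adjusted p up to 0.082 (bleomycin 24 h b). Ccl8 (2.63), Cpxm1 (2.24), Thy1 (1.86), Tnc (1.80), C1qa (1.65) and Col5a2 (1.41) also gained, as did Get4 (2.94), Lsm2 (2.46), Mast2 (2.41) and Tyro3 (2.33). Smaller at 14 d were H2-Bl (-2.58), an MHC class I gene, and bright probe sets such as Ctsd (-3.76). Sct (-2.63), Tbc1d10a (-3.05) and Phf7 (-2.76) were called by one probe set, and not by another (-0.49, -0.23 and -0.28). Tgfb1 (1.19, adjusted p = 0.125), Fn1 (-1.55, adjusted p = 0.0901), Timp1 (0.00), Col1a1 (0.70), Col3a1 (0.56), Cdkn1a (-0.31), Acta2 (0.30) and Blmh (-0.51) were not called. Of the 2 other probe sets for Col3a1 (1.5 and 0.06), 1 was called higher here too. The cell cycle list had 12 of 41 genes higher, 15 adjusted over the list alone (camera adjusted p = 5.32e-06, and adjusted p = 0.419 with an estimated correlation), and collagens 4 of 38 higher and 1 lower (0.0243, and 0.419). In all 433 probe sets were called, 263 higher and 170 lower. With 1 array left out there were 18 or 281 (bleomycin 24 h b or a), 44 or 1111 (bleomycin 14 d b or a), 62 or 64 (saline 14 d b or a) and 163 or 261 (saline 24 h a or b).

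Averaged over the 3 times, C57BL/6J lungs showed chemokine, macrophage and p53 genes higher after bleomycin. As labelled, and then over 24 h and 14 d without the saline arrays of 72 h, Ccl2 rose by 3.12 ± 0.42 and 2.66 ± 0.54, Arg1 by 2.51 and 2.15, Ccl8 by 2.02 and 1.99, and Cdkn1a by 1.52 and 1.57. Timp1 (1.15, adjusted p = 0.00595) and Col3a1 (0.71, adjusted p = 0.00325) were called as labelled, and not without those arrays (1.03, adjusted p = 0.0842, and 0.50, adjusted p = 0.15). The complement gene Hc (-1.80 and -1.98), Tff2 (-1.54 and -2.04), Pon1 (-1.53 and -1.61) and Cyp1a1 (-1.46 and -1.47) were lower in both forms. Cldn4, a tight junction gene, rose by 1.34 and 1.86, and Mmp12 by 1.19 and 1.71. In the p53 list 11 of 17 genes rose and 1 fell as labelled (camera adjusted p = 9.17e-09, and 0.014 with an estimated correlation; 9 rose without). Macrophage markers rose for 11 of 24 (7 without). B and plasma cell genes (7 of 13 fallen, 4 without), endothelial genes (9 of 25 fallen, 8 without) and heart and muscle genes (9 of 17, 4 without) were lower in both forms. With an estimated correlation only the p53 list of the 17 called held. As labelled 1226 probe sets were called, 648 higher and 578 lower, and 426 without those arrays; without the C57BL/6J saline 24 h a array the count was 774.

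Averaged over the 3 times in BALB/c, Ccl8 rose by 1.63 ± 0.16 as labelled and 1.43 without the saline arrays of 72 h, Bcl3 by 1.62 and 1.70, and Cdkn1a by 1.44 and 1.36. Itgb4 rose by 1.21 and 1.45, H1f10 by 1.30 and 1.53 and Kng1, kininogen, by 1.28 and 1.38. H1f10 was not called with the strain labels of those arrays exchanged (0.91, adjusted p = 0.0655). Sct fell in both forms (-1.87 and -2.79), but its second probe set did not as labelled (-0.06). Zfp94 fell in both forms (-1.73 and -2.56). Tgfb1 (0.48 and 0.68), Timp1 (0.19 and 0.03), Col1a1 (0.27 and 0.40), Col3a1 (0.09 and 0.10), Fn1 (-0.50 and -0.68), Acta2 (0.34 and 0.49) and Blmh (-0.20 in both) were called in neither form. The p53 list had 8 of 17 risen and 1 fallen (1.26e-04 as labelled, 0.123 with an estimated correlation; 7 risen without), and the alveolar type 1 (4 of 9 fallen, 0.00194) and type 2 lists (1 of 12, 0.00101) were lower, neither with an estimated correlation (adjusted p = 0.137 and 0.265). As labelled 525 probe sets were called, 325 higher and the others lower, and 378 without those arrays, 289 of them shared. Leaving out 1 array moved the count to between 245 (bleomycin 72 h b) and 329 (saline 24 h a) for 9 arrays and to 796 without the bleomycin 14 d a array.

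The strain difference averaged over the times included Arg1, larger in C57BL/6J by 2.60 ± 0.33 as labelled and 2.04 ± 0.42 without the saline arrays of 72 h (adjusted p = 2.15e-04 and 0.0353). Sct (2.29 and 3.64), Gfpt2 (1.29 and 1.43), an enzyme of the hexosamine pathway, and the chemokine receptor Ackr3 (1.27 and 1.31) were higher in both forms, while the second probe set for Sct was not called as labelled (0.43, adjusted p = 0.344). H3c14 (-1.74 and -2.29), Cdh13 (-1.34 and -1.75), Lrp5 (-1.59 and -1.51) and Zfp57 (-1.24 and -1.46) were lower. Lrp5 was not called with the strain labels exchanged (-0.80, adjusted p = 0.112). Tgfb1 (-0.63), Timp1 (0.96), Col3a1 (0.62), Col1a1 (0.18), Fn1 (0.34), Cdkn1a (0.08), Acta2 (-0.17) and Blmh (0.27) did not differ by test. Of the 12 lists called as labelled, the interferon list had 5 of 27 genes higher (2.2e-04; 1 without those arrays, 0.0409), the protease list 1 of 18 (0.004; 0.0167 without) and macrophage markers 1 of 24 (2.2e-04; 0.0167 without). None held with an estimated correlation. As labelled 334 probe sets were called, 127 higher and 207 lower, 86 without those arrays and 83 with their strain labels exchanged. Leaving out 1 array gave 183 and 222 (BALB/c bleomycin 72 h a and 24 h b), 208 (BALB/c saline 14 d b), 197 (C57BL/6J bleomycin 72 h a), 212 (C57BL/6J saline 24 h a) and 577 (C57BL/6J bleomycin 14 d b).

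After saline alone the strains differed in single genes of several kinds. As labelled, and then without the saline arrays of 72 h, H2-Ea was lower in C57BL/6J by -1.96 and -5.32, the guanylate binding protein Gbp2b by -1.14 and -3.35 and Fbp2, a muscle fructose bisphosphatase, by -1.05 and -2.65. One probe set for Pdxdc1 was lower (-1.43 and -4.43) and 2 others were higher as labelled (0.58 and 0.47). Higher in C57BL/6J were Bcl3 (1.44 and 1.68), Lrp5 (1.34 and 1.42), Mir686 (0.94 and 2.59), the chitinase-like Chil3 (0.69 and 2.06) and one probe set for Qsox1 (0.88 and 2.07; another 0.03 as labelled). Tgfb1 was higher in C57BL/6J in both forms (0.78 ± 0.18, adjusted p = 0.0322, and 1.02 ± 0.23, adjusted p = 0.0112; 6 arrays against 6, and 4 against 4). As labelled the call ended when any of 8 of the 12 arrays was left out singly, with adjusted p up to 0.102 (C57BL/6J saline 14 d a). With the strain labels of the 72 h arrays exchanged neither Tgfb1 (0.58, adjusted p = 0.0559) nor Lrp5 (0.55, adjusted p = 0.052) was called. Col1a1 was higher without the 72 h arrays only (0.43, adjusted p = 0.189, and 0.85, adjusted p = 0.0205). Blmh did not differ (-0.12 and -0.09), nor did Timp1 (-0.27), Col3a1 (-0.27), Fn1 (0.05), Cdkn1a (0.44) or Acta2 (0.31). A strain difference on such arrays can also come from sequence differences under the probes. As labelled only the cell cycle list was called, lower in C57BL/6J with 0 of 41 genes called by limma and 2 unadjusted (0.0381, and adjusted p = 0.872 with an estimated correlation), and none without. As labelled 232 probe sets were called, 147 higher and 85 lower; without the 4 arrays 878 were, 468 higher and 410.0 lower, 214 of them shared. With the strain labels of the 72 h arrays exchanged 829 were called. Leaving out 1 array gave 95 (the array labelled C57BL/6J saline 72 h a), 110 (C57BL/6J saline 14 d a) and 149 (C57BL/6J saline 24 h a). For BALB/c it gave 97 and 105 (BALB/c saline 14 d a and b), 154 and 146 (BALB/c saline 24 h a and b) and 153 (the array labelled BALB/c saline 72 h b).

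The lists of the TGF-beta pathway, oxidant defence, fat and mesothelium, thymus and the circadian clock were called in none of the 15 comparisons, with lowest camera adjusted p values of 0.0538, 0.269, 0.216, 0.125 and 0.146.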

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

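The tests of the 72 h saline arrays and of the brightest probe sets were chosen only after the result was seen, and so were the setting with the C57BL/6J saline 14 d arrays as the 24 h control and every test with the strain labels of the 72 h saline arrays exchanged, splits included. The interferon tests and the splits of the arrays as labelled were laid down before their results were seen. A test of the difference itself brought out 6 comparisons. The bleomycin effect differed between the strains for 2 probe sets and 8 gene lists at 24 h, for 268 probe sets and 8 lists at 72 h, for 647 probe sets and 5 lists at 14 d, and for 334 probe sets and 12 lists on average over the times. Between 24 h and 14 d the effect changed for 236 probe sets and 14 lists in C57BL/6J and for 433 probe sets and 2 lists in BALB/c. The 72 h values and the averages use the saline arrays of 72 h as labelled.

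The saline arrays of 72 h carried the signature of the other strain. Mixed RNA would have placed the 4 arrays part of the way between the strains, yet all lay between 87.8% and 100.3% of the way to the other one. Regulation after saline is argued against because 98.4% of the panel genes had the opposite order of the strains, and bleomycin-treated animals because the arrays lay at most 26.6% of the way from saline to bleomycin on the p53 list. An exchange of the strain labels between the 2 groups, for which each group supplies the partner, stays open and meets what it requires, with 87.8% as the lowest position, though it was not checked against any record. With the labels exchanged the strain difference in the 72 h effect had 0 probe sets called by limma (561 at an unadjusted p under 0.05), that in the averaged effect 83, the 72 h effect 226 in C57BL/6J (576 as labelled) and 7 in BALB/c (115 as labelled).

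The brightest probe sets, chosen by their mean on the C57BL/6J saline 24 h arrays, read higher there than on the other 22. That choice by itself favours higher values there, and the CreX spike did not enter it. Loss of bright transcripts after bleomycin is argued against by the other 10 saline arrays, whose highest Sftpc value was 6967 against 43230 on the lower of the 2 arrays. A difference between arrays in how bright signals were measured stays open: the mean of the CreX spike, which does not come from the lung, was 1.52 times the highest value elsewhere, while the dimmer BioB (823 to 1043) and BioC (1111 to 1520) spikes lay within the range of the other arrays. A ceiling near the top of the other 22 arrays also stays open for the brightest probe sets as a set. Their array medians reached 53.9% to 87.7% of the level it would leave, and 53.9% to 76% of the array maximum for those above it. Sftpc and Hba-a1 had medians of 481 and 390 on those arrays, far below any array maximum (at least 6888). A ceiling on the deposited values would not leave them there. A ceiling on single probes cannot be judged from these values, since the algorithm that summarised the probes is not given. The source of such a difference and a difference in saline-treated lungs of this strain at 24 h were not tested.

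The interferon list rose more in C57BL/6J than in BALB/c at 24 h, with a median log2 difference of 0.59. The C57BL/6J saline 24 h control arrays are argued against as the source, since with the saline 14 d arrays in their place the median was 0.60 (camera adjusted p = 2.55e-11). The median was 0.73 without the BALB/c saline 24 h b array (9.61e-13) and 0.48 without the C57BL/6J bleomycin 24 h a array (1.16e-06), so neither array alone accounts for the list, though the call of Isg15 ended without the latter (1.52, adjusted p = 0.157, with 1 array left in that group). With an estimated correlation the list was not called (adjusted p = 0.127), so genes that vary together are a further open source. A stronger interferon response of C57BL/6J lungs is a hypothesis that may be tested on other animals, and differences in handling between the strains were not tested.

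Splits of the arrays into groups of the same sizes, 100 for each comparison with the real one included, asked whether chance could give as many calls. For the averaged bleomycin effect in C57BL/6J only 1 of the 100 splits, the real one, reached 1226 probe sets, with 860 as the highest other. In BALB/c it was also 1, the real one with 525, but the highest other had 524. For the strain difference in the averaged effect it was 1, with 334 against 56. With the strain labels of the 72 h saline arrays exchanged the splits, again 100 each, gave 1 for C57BL/6J (1032 against 540 as the highest other), 2 for BALB/c (409 against 671) and 1 for the strain difference (83 against 5). As labelled, splits of the arrays thus argue against chance for C57BL/6J and the strain difference. They cannot exclude chance between animals, since a and b may not be separate animals. The 334 also rest on the 72 h saline arrays that carry the other strain's signature. The exchanged form was chosen after that signature was seen, so its ranks are given as values only. In BALB/c the share of splits points the same way, but narrowly. The highest other split lay at 524 against 525 as labelled, and above the real one with the labels exchanged. For the strains after saline 7 splits called at least the 232 of the real one, so chance cannot be excluded as labelled. With the labels exchanged only 1 split, that grouping itself, reached 829, with 505 as the highest other. The exchange was chosen after strain-separating genes were seen in reverse on these arrays, so its rank among the splits cannot exclude chance. The highest other as labelled, 829, equals the count with the strains of the 72 h saline arrays exchanged, which points to a structure of the samples.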

How the results depend on the processing

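The tests without the 72 h saline arrays, with their strain labels exchanged, without the brightest probe sets and with the C57BL/6J saline 14 d arrays as the 24 h control were chosen only after the result was seen. Log2 changes of named genes over the settings laid down at the start, single arrays apart, stayed on the same side of the threshold in 7422 cases, became weaker in 555 and stronger in 17, and turned in 6. Under the added ones the numbers were 2050, 391, 5 and 77, and with 1 array left out 18357, 2225, 42 and 0. Genes that were not called changed sign in 18, 23 and 64 cases. With 1 array left out the lone array of its group is assumed to vary like the other groups. Between 71.8% and 77.6% of probe sets on an array lay above the offset of 92, and changes of dimmer ones are held small by it. The cause was not tested for the moves below, except that fewer arrays or probe sets enter where some are left out.

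Quantile normalization gave 121 calls in C57BL/6J at 24 h and 34 in BALB/c at 24 h, against 194 and 19. A 3 times larger offset gave 11 for the strain difference at 24 h against 2, and no filter 12 in BALB/c at 24 h. Array weights gave 942 in C57BL/6J at 72 h, 175 in C57BL/6J at 14 d, 252 in BALB/c at 72 h, 4, 455 and 150 for the strain difference at 24 h, 72 h and 14 d, and 116 for the change in C57BL/6J. With all saline arrays of a strain as control the counts were 406 and 1451 in C57BL/6J at 24 h and 14 d, and 228 and 190 in BALB/c at 24 h and 72 h, Sftpc turned to 0.021 in C57BL/6J at 24 h and Gsto1 to 0.46 in BALB/c at 72 h. The arrays of C57BL/6J alone gave 84, 354 and 295 at 24 h, 72 h and 14 d. Without the 24 h groups the BALB/c average had 936, Ly6e (0.14) and Rpl41 (1.18) turned in the C57BL/6J average, and Pdxdc1 (0.12) and Baiap2l1 (0.26) turned between the strains after saline. With an estimated correlation 13 of the 133 list calls were left.

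Without the 72 h saline arrays the counts were 426 (C57BL/6J average), 10 and 526 (BALB/c at 24 h and 72 h), 5, 79 and 86 (strain difference at 24 h, 72 h and on average) and 878 (strains after saline). In C57BL/6J at 72 h H2-Ea (0.022), Fbp2 (0.038), Cxcl14 (-0.38) and Flt4 (0.25) turned, and in the average Reg3g (-0.029). In BALB/c at 72 h H2-Ea (-0.35), Baiap2l1 (-0.047), Rbfox2 (0.14), Bpifb1 (0.28), Plau (-0.30), Chil3 (0.19) and Gsto1 (0.96) turned, and in the average H2-Ea (-0.39). In the strain difference at 72 h Arl2bp (-0.20), Chil3 (-0.14), H2-Ea (0.37), Fbp2 (0.008), Cap1 (0.49), Gatm (0.16), Serpinh1 (-0.006), Plau (0.06), Gsto1 (-0.62), Procr (0.94), S100a10 (-0.031), Jchain (0.18), Reg3g (-1.95) and Klf2 (-1.56) turned, and on average Arl2bp (-0.051), H2-Ea (0.78), Gbp2b (0.04), Fbp2 (0.16) and Chil3 (-0.018). Without the brightest probe sets C57BL/6J at 24 h had 126. With the C57BL/6J saline 14 d arrays as its control C57BL/6J at 24 h had 460, 73 of them shared, and the strain difference 15; Rpl41 (1.21), Ly6e (0.38), Hba-a1 (0.63), Snrpb (1.18), Sftpc (2.28), Scgb1a1 (1.02), Gstm1 (0.17), Ager (0.091), Kdr (0.14), Rag1 (0.12) and Hspa1a (-0.18) turned.

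With the strain labels of the 72 h saline arrays exchanged the counts were 226 and 7 (C57BL/6J and BALB/c at 72 h), 0 by limma (561 at an unadjusted p under 0.05) and 83 (strain difference at 72 h and on average) and 829 (strains after saline). In C57BL/6J at 72 h Reg3g (-0.063), Erdr1 (0.124), Plau (0.084) and Flt4 (0.084) turned, and in the average Reg3g (-0.04). In BALB/c at 72 h H2-Ea (-0.023), Erdr1 (-0.273), Baiap2l1 (-0.058), Mir686 (0.091), Arl2bp (0.011), Bpifb1 (0.077), Chil3 (0.55) and Gsto1 (0.612) turned, and in the average H2-Ea (-0.265). In the strain difference at 72 h Arl2bp (-0.197), Chil3 (-0.143), Epb41l4a (-0.02), Erdr1 (0.397), Cap1 (0.165), Gatm (0.395), Serpinh1 (-0.121), Plau (0.019), Clca1 (-0.096), Gsto1 (-0.467), Gstm2 (0.049), Procr (0.806), S100a10 (-0.148), Reg3g (-2.539), Flt4 (0.245), Klf2 (-1.091) and Fos (-0.455) turned, and on average Arl2bp (-0.099), H2-Ea (0.451) and Chil3 (-0.06). Lrp5 (0.63) also changed sign in the strain difference at 72 h.

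Leaving out each array in turn moved the counts between 38 and 269, 222 and 686, 87 and 1249, and 774 and 1542 for C57BL/6J at 24 h, 72 h, 14 d and on average. For BALB/c the ranges were 1 to 52, 52 to 133, 198 to 1444 and 245 to 796, and for the strain difference 0 (by limma, with 564 and 648 at an unadjusted p under 0.05 in the 2 cases) to 27, 154 to 316, 136 to 1014 and 183 to 577. The strains after saline had 95 to 308, and the change from 24 h to 14 d 69 to 848 in C57BL/6J and 18 to 1111 in BALB/c.

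With the array letter as a replicate block the counts were 183, 532, 620 and 1144 in C57BL/6J and 18, 103, 1082 and 458 in BALB/c at 24 h, 72 h, 14 d and on average, 3, 260, 568 and 266 for the strain difference, 222 for the strains after saline, and 205 and 397 for the changes. Deviations of arrays with the same letter correlated between -0.285 and 0.309 over 66 pairs of groups, with 14 over 0.1, so the letters do not pair the arrays.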

Other observations

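The test of the clock genes was chosen only after the result was seen. In BALB/c at 14 d after bleomycin the clock outputs Dbp (-2.39 ± 0.41, adjusted p = 0.00176), Nr1d2 (-1.65 ± 0.21, adjusted p = 2.78e-04) and Nr1d1 (-0.98, adjusted p = 0.017) were lower, and Arntl, which drives them, was higher (1.28 ± 0.18, adjusted p = 5.65e-04). In C57BL/6J at 14 d Nr1d1 was lower (-1.08, adjusted p = 0.0139) and Bhlhe40 (1.11) and Cry1 (0.86) higher, while Arntl was not called (-0.14). In C57BL/6J at 72 h, as labelled and then without the saline arrays of 72 h, Dbp (-2.08 and -1.29), Nr1d1 (-1.40 and -1.54) and Nr1d2 (-1.07 and -0.68, adjusted p = 0.0361; not called with the strain labels of those arrays exchanged, adjusted p = 0.0512) were lower in both forms, and Arntl was higher as labelled only (0.93, adjusted p = 0.00419, and 0.25, adjusted p = 0.329). The strains differed at 14 d in Arntl (-1.42, adjusted p = 0.0057) and Nr1d2 (1.05, adjusted p = 0.0395), and not by test in Dbp (1.77, adjusted p = 0.0686), and at 72 h as labelled in Arntl with the opposite sign (1.36, adjusted p = 0.00444, and 0.43, adjusted p = 0.328, without those arrays). These genes were chosen after their values were seen.

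A shift in clock phase between the bleomycin and saline arrays of BALB/c at 14 d would move the day-phase genes together. The median of Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp and Tef was -0.69. Of the 7, 6 had negative values, but only Dbp, Nr1d1 and Nr1d2 were called. Per2 (-0.27), Per3 (-0.38) and Tef (-0.69) were not, and Per1 was at 0.19. A shift may account for the called genes. The hour at which lungs were taken is not among the labels used here, so a difference in that hour and a clock shifted by injury both stay open.

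The metallothionein Mt1 was higher after bleomycin in C57BL/6J at 14 d (1.88, adjusted p = 0.0372) and not called in BALB/c (1.14, adjusted p = 0.163). Cyp1a1, an enzyme of xenobiotic metabolism, was lower in C57BL/6J at 24 h (-1.73, adjusted p = 0.00104) and 14 d (-1.21, adjusted p = 0.00811). Irf9, which carries the interferon signal to the nucleus, fell at 14 d in C57BL/6J (-0.92, adjusted p = 0.00357) and rose in BALB/c (0.60, adjusted p = 0.0261), a difference of -1.52 (adjusted p = 0.00305). Mt1 and Irf9 were chosen after their values were seen.

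The actin 3' control probe set read 38421 and 50282 on the 2 C57BL/6J saline 24 h arrays and 134 to 10915 on the others. The ratio of the 3' to the 5' Gapdh control ranged from 0.583 to 2.16 over the 24 arrays. Uty, also Y-linked, read 10.2 to 103.5.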
